A study of Mus musculus with 2 samples.

How the data were processed

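Genomic DNA of mouse peripheral blood cells had been measured by reduced representation bisulfite sequencing (RRBS), in which DNA cut with MspI at CCGG sites is treated with bisulfite, so that unmethylated cytosines are read as T and methylated ones as C. There were 2 libraries, 1 from a wild-type (WT) mouse and 1 from a mouse expressing I-PpoI, a homing endonuclease that makes double-strand breaks, in proximal tubular epithelial cells of the kidney. Per the labels' protocols, the libraries were made with a Zymo-Seq RRBS kit. Per the submitters' processing notes, methylKit was used, with no version given. The aligner, the genome build, trimming and any removal of duplicate reads are not given in the sources used here.

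Per the file headers, the coverage column gives the count of reads over each cytosine of a CpG on its own strand, and the deposited percent columns give the share of those reads with C and with T. Percent C times coverage was a whole number, within 1e-06, at 100% of cytosines in both libraries, so methylated read counts were recovered from the deposited percent values and the counts. No cytosine with fewer than 10 reads was listed. Regions found with MACS, the motif search with MEME and the fold rule named in the design text were the submitters' own steps; neither MACS nor MEME was run here. The fold rule was tried as an alternative.

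Cytosines covered by at least 10 reads in both libraries were used, on the autosomes and X. Cytosines above the 99.9th percentile of coverage of a library, which was 284 reads in WT and 252 in I-PpoI, were left out. Reads were summed over windows of 1000 bp with at least 3 such cytosines, and methylated and unmethylated reads of both libraries were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. A window or a single cytosine was called at an adjusted p under 0.01 and a difference of at least 25 percentage points. For gene regions the minimum was 10 points. These rules, the gene lists and the rule for naming genes were fixed before the data were examined.

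Gene symbols and the order of genes along chromosomes came from a RefSeq gene table of the assembly GRCm38.p6. The table gives no strand, so the planned promoter, 1000 bp either side of the 5' end, was replaced by the region within 1000 bp of whichever annotated gene end held more measured cytosines; this choice was made after the data were seen. The richer end held at least 2 times the cytosines of the other in 94.3% of genes, and 150 genes had a tie. A gene body is the stretch between the end regions. Whether the table and the libraries share a build was tested by shifting the gene ends. Mean WT methylation was 10.9% at the gene ends and between 31.5% and 33.2% at ends shifted by 5000 to 100000 bp, and was lowest with no shift on 20 of 20 chromosomes. Window positions below are those of the deposited values, counted from 1, and no coordinates of the gene table are given. Of 334 list symbols, 333 were matched by symbol or by a synonym held by 1 gene alone. Rigi was the exception. A genome sequence was not used here, so the planned searches for motifs, CpG islands and I-PpoI recognition sites, and the asymmetric promoter, were not run.

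There were no replicates. A Fisher test on the reads of 2 libraries compares those libraries, not the conditions, and no p-value was computed across genes or windows. Gene lists were described by the percentile of their median difference among 10000 random lists of the same size, matched on methylation level and number of cytosines. Single levels carry Wilson 95% intervals and differences carry Newcombe 95% intervals. Reads were PCR copies without molecular identifiers as far as the labels say, so these intervals cover no more than counting error. Read counts of a region are sums over its cytosines, so a read that spans several cytosines is counted at each. The tests and intervals treat these counts as independent. They are too narrow where cytosines on the same read are alike.

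Windows were named as the 8 called windows with the largest rise and the 8 with the largest fall that overlapped or bordered a protein-coding gene, held at least 5 cytosines and 100 reads per library, and had at least 80% of cytosines moving the same way. The same minimums gave the 5 gene ends of protein-coding genes named each way. From each list up to 4 called members were named, by size, or up to 2 with the most reads where none was called. Any other feature named was chosen after its values were seen.

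Alternatives changed the coverage minimum, coverage cap, strand, depth, chromosomes, thresholds, weighting, test, window length and phase, cytosine minimum and list matching. One alternative replaced Fisher's test with a Cochran-Mantel-Haenszel test over cytosines divided by the spread between cytosines of a region (the scaled test below). The window tests were tested on simulated data for the 165854 windows of WT against I-PpoI, with 200 changed windows. With binomial reads, Fisher's test called 0% of drops of 15 points, 85.1% of drops of 30 points and 100% of drops of 45 points, and 7 unchanged windows. With reads more variable than binomial it called 117 unchanged windows. The scaled test called no unchanged window in either case, and with binomial reads 37.3% of drops of 30 points and 34.8% of drops of 45 points. The simulation drew each cytosine independently, so it held no error shared by cytosines on the same reads. Its counts of unchanged windows called are therefore not false-call rates for the real libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Numba 0.67.0 and matplotlib 3.10.9 were used.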

Results

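RRBS of peripheral blood cells was compared between 1 WT mouse and 1 mouse with I-PpoI expressed in the proximal tubule, to ask whether blood DNA methylation differs when DNA breaks are made in the kidney. The WT library listed 3569384 cytosines with a median coverage of 53 reads, and the I-PpoI library 3141563 cytosines with a median coverage of 49. Their summed coverage was 245819308 and 203696298 reads over cytosines. Both libraries listed 3040450 of these cytosines, and 3026647 were used after filtering. Both also listed cytosines on the Y chromosome, 11963 in WT and 10327 in I-PpoI. Y held 0.486% of reads over non-mitochondrial cytosines in WT and 0.238% in I-PpoI, while X held 1.33% and 1.24%. The cause of the lower Y share in I-PpoI was not tested.

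The I-PpoI library had a slightly lower mean methylation level than the WT library, and the difference was largest at partly methylated cytosines. The mean level over shared cytosines was 38.6% in WT and 37.1% in I-PpoI, a difference of -1.49 percentage points. The median difference was 0, with 41.7% of cytosines lower in I-PpoI, 29.2% higher and 29.1% equal. Cytosines between 20 and 80% methylated averaged 54.0% in WT and 48.0% in I-PpoI, and 61.3% of them were lower in I-PpoI. Levels were classed by the mean of both libraries, so a large difference itself moves a cytosine towards this middle class. The difference was -0.837 points at cytosines under 20% and -0.914 points at those over 80%. Across cytosines, which are not independent replicates, the levels correlated with r = 0.976, and 83.8% lay within 10 points of each other. The pooled share of methylated reads was 30.6% in WT (95% Wilson interval 30.62 to 30.64) and 24.3% in I-PpoI (24.32 to 24.33). With WT coverage applied to I-PpoI levels the latter became 29.4%, so 20.1% of the pooled difference was left.

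Regions that differed were mostly lower in the I-PpoI library. Of 165854 windows tested, 1663 were called lower and 123 higher, so that 93.1% of calls were lower. Single cytosines gave 12986 lower and 1698 higher calls among 3026647. Lower calls outnumbered higher ones on 20 of 20 chromosomes, and the mean difference of autosomes ranged from -2.64 to -2.15 points, with -1.81 on X. By the mean level of both libraries, windows of 40 to 60% showed a mean difference of -6.60 points, against -0.497 under 5% and -0.219 over 95%. Such classing leaves less room to differ near 0 and 100%. Windows at gene ends were called lower in 0.435% of cases, against 1.18% inside genes and 1.08% between genes. Windows with 3 to 5 cytosines were called lower in 1.97% of cases and those with over 50 cytosines in 0.0637%. These classes did not start alike, and a window whose WT level is under the minimum difference cannot be called lower. Mean WT levels were 28.8% at gene ends, 76.6% inside genes and 79.6% between genes. They were 82.0% with 3 to 5 cytosines and 7.61% with over 50. Whether the classes differ at like WT level was not tested. The scaled test called 129 lower and 4 higher windows.

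**Figure D1:**
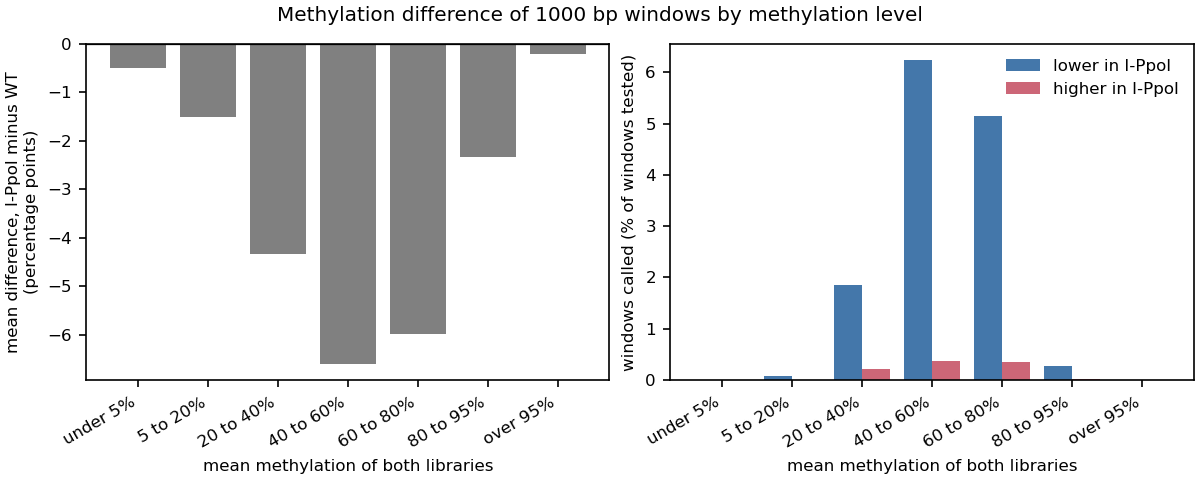
Left, mean difference in methylation (I-PpoI minus WT, percentage points) of 1000 bp windows by the mean level of both libraries; right, the percent of windows called lower or higher in I-PpoI. The mean difference is largest in windows of 40 to 60%, at -6.60 points, where 6.24% of windows are called lower and 0.374% higher.

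Among windows at protein-coding genes that met the minimums for naming, the largest losses were found in Snx11, Grhl1 and Lcp2. A window at 11:96772001-96773000 inside Snx11, a sorting nexin gene, fell from 88.4% in WT to 25.1% in I-PpoI, a difference of -63.3 points (95% Newcombe interval -69.3 to -56.1; Fisher's exact test, adjusted p = 6.1e-49) over 9 cytosines with 285 and 239 reads. A window at 11:34053001-34054000 inside Lcp2, which encodes the adaptor SLP-76 of T cell receptor signalling, fell from 68.3% to 13.0% (Fisher's exact test, adjusted p = 2.0e-16). Windows inside Lasp1 (11:97815001-97816000), whose product binds actin, and Rin3 (12:102362001-102363000), a RAB5 exchange factor gene, fell from 78.5% to 24.7% and from 67.5% to 14.3%. The window at 9:21835001-21836000 lay at the gene end of Angptl8, a regulator of lipoprotein lipase, inside Dock6, and fell from 70.3% to 16.1%. Grhl1 (12:24608001-24609000) fell from 79.0% to 22.2% and Rusc2 (4:43425001-43426000) from 82.5% to 31.4%. Mid1 (X:169986001-169987000), a gene that spans the pseudoautosomal boundary in laboratory mice, fell from 56.0% to 5.44% over 11 cytosines.

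Among windows at protein-coding genes that met the same minimums, the largest gain lay at Pgk1, the X-linked gene of the glycolytic enzyme phosphoglycerate kinase 1. Its adjoining windows at X:106186001-106187000 and X:106187001-106188000 rose from 5.16% (3.82 to 6.92) to 43.8% (41.5 to 46.2) and from 3.76% (2.67 to 5.25) to 36.2% (33.8 to 38.6), with adjusted p of 5.4e-97 and 1.0e-81 by Fisher's exact test. The first had 795 reads in WT and 1728 in I-PpoI, the second 852 and 1598. Gains inside genes were found at Celf4 (18:25643001-25644000), an RNA-binding protein gene, from 39.7% to 73.4%, at Mospd1 (X:53364001-53365000), from 28.2% to 60.2%, and at Cnbd2 (2:156363001-156364000), from 57.4% to 89.3%. Clasp1 (1:118457001-118458000), a microtubule-binding protein gene, rose from 50.2% to 80.9%. Ube2d1 (10:71258001-71259000), which encodes a ubiquitin-conjugating enzyme, rose from 40.8% to 71.5%, and Ssc5d (7:4933001-4934000) from 37.0% to 67.3%. Of the 16 windows named, 5 were also called by the scaled test, those of Snx11, Angptl8, Rin3, Mid1 and the second of Pgk1. On forward-strand cytosines alone the first Pgk1 window differed by 10.1 points, Ube2d1 by 20.4 and Ssc5d by 16.7, below the 25 points asked.

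**Figure D2:**
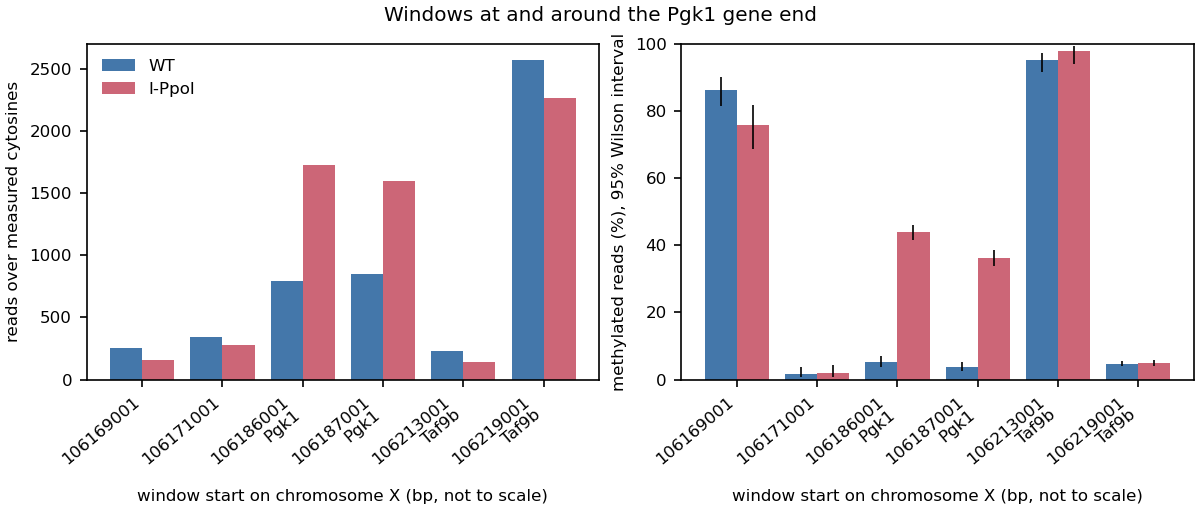
Reads over measured cytosines (left) and percent of methylated reads with 95% Wilson intervals (right) in the windows at and around the Pgk1 gene end on X, for WT and I-PpoI. The Pgk1 windows have 1728 and 1598 reads in I-PpoI against 795 and 852 in WT, while the windows on both sides have fewer reads in I-PpoI than in WT.

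**Figure D3:**
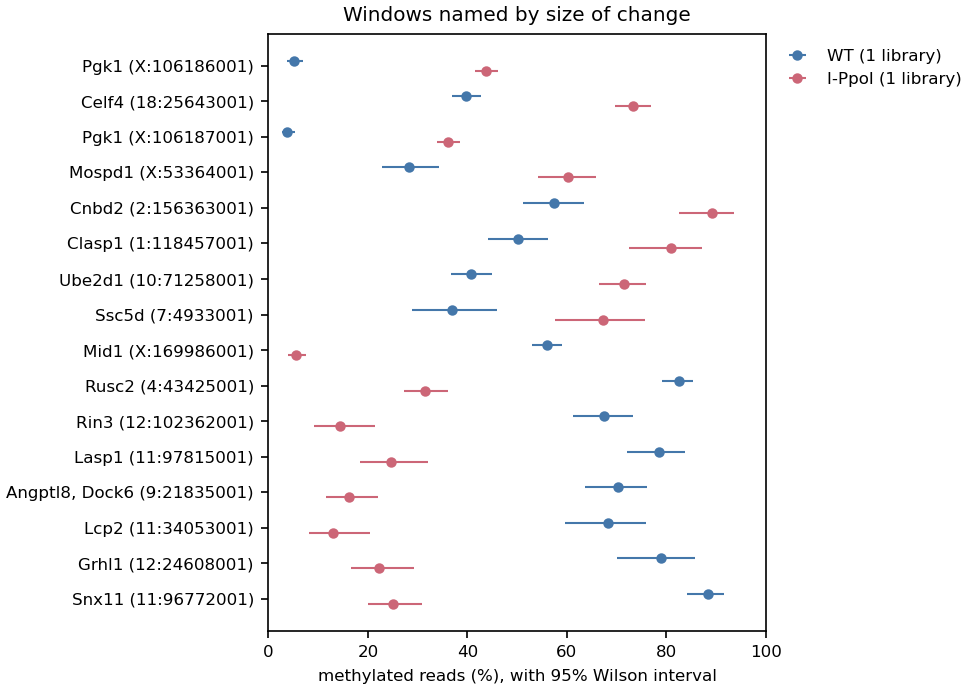
Methylation level (percent of reads, x axis) of the 16 named windows in WT and I-PpoI, 1 library each, with 95% Wilson intervals that cover no more than counting error. The Pgk1 windows start from 5.16% and 3.76% in WT, while the other windows that rose start between 28.2% and 57.4%.

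At gene ends, 277 of 15256 genes were called lower and 34 higher. After Angptl8, the largest losses among protein-coding genes that met the minimums for naming were at Atg4c, an autophagy protease gene, from 49.2% to 8.13%, and Prr15l, from 44.3% to 7.02%. Rps6kc1, a ribosomal S6 kinase family gene, fell from 58.9% to 26.6%, and Dapp1, which encodes a B cell adaptor that binds phosphoinositides, from 92.2% to 60.3%. The gene end of Pgk1 rose from 4.43% to 40.1% over 35 cytosines (difference 35.7 points, 33.7 to 37.6; Fisher's exact test, adjusted p = 3.8e-182). Gene ends of Lamtor3-ps, listed as protein-coding in the gene table, the Wnt antagonist gene Dkk4, the neuronal microtubule gene Dcx and the sorting nexin gene Snx20 rose by 30.8, 23.5, 19.98 and 16.8 points. With reverse-strand cytosines alone Rps6kc1 was no longer called (-14.8 points), and with forward-strand cytosines alone neither was Dcx (13.0 points). The scaled test did not call Rps6kc1, Dkk4, Dcx or Snx20. Among gene bodies 1253 of 13779 were called lower and 34 higher.

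Gene body levels depended on coverage as well as on methylation. A body's level pools reads over cytosines that can differ widely in level, and methylated cytosines had lost more coverage in I-PpoI: at cytosines within 5 points of each other the median read ratio of I-PpoI to WT was 0.929 under 20% and 0.702 over 80%. With each cytosine weighted equally, an alternative fixed before the data were examined, 456 bodies were called lower and 27 higher, against 206 and 23 gene ends. Equal weights change the difference alone, and the p-value stays that of Fisher's exact test on pooled reads. The median difference over all genes was then -1.55 points in bodies, in place of -2.52, and -0.630 at gene ends, in place of -0.617. List percentiles by equal weights were added after the data were seen. They are given below where a median crossed a bound of the middle 95% of random lists, and equal-weight differences where a named gene lost its call. Other percentiles shifted too and, apart from those set beside the test of cell mix, are not given.

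Neutrophil genes had more gene ends called lower than the other blood cell lists, but their medians lay inside the middle 95% of random lists. The lists also did not start alike, and a gene end under 10% in WT cannot be called lower. The median WT level of gene ends was 8.61% to 33.0% in the other blood cell lists and 66.9% in neutrophil genes. Of 11 gene ends measured, 4 were called lower and none higher, among them Ctsg, the granule protease cathepsin G (82.7% to 58.8%), Camp, the antimicrobial cathelicidin (93.0% to 71.0%), and Cebpe, a transcription factor of granulocyte maturation (67.5% to 45.9%). Of 10 bodies 3 were called lower, with the largest difference at Mmp8, neutrophil collagenase, from 83.9% to 44.9% over 5 cytosines. The same numbers, 4 and 3, were called lower with equal weights. Adjusted over the list alone, 4 gene ends were called lower and 1 higher. The median was -4.99 points at gene ends, at percentile 6.555 of matched random lists, and -5.12 points in bodies, at percentile 6.63. The mean over bodies lay at percentile 0.16, and by equal weights the median over bodies lay at percentile 0.41. In the scaled test the Mmp8 body and the gene ends of Camp and Ctsg lost their calls and the gene end of Cebpe kept its own. Camp was not called at a coverage minimum of 20 reads (-11.8 points). Among monocyte and macrophage genes 1 of 8 gene ends was called lower, Adgre1, which encodes the macrophage antigen F4/80 (80.8% to 54.7%), which was not called in the scaled test. Of 11 bodies 2 were called lower, Cd86, a costimulatory ligand gene, and Spi1, encoding the myeloid regulator PU.1, by 12.4 and 10.1 points, but neither was called by equal weights (-7.13 and -4.55 points). The medians of this list stood at percentiles 63.2 and 92.7.

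Lymphoid marker lists stayed within the range of their random lists. Of 15 T cell gene ends 1 was called lower, and none by equal weights. Of 19 bodies 3 were called lower by pooled reads: Lck, the T cell receptor kinase (33.7% to 21.1%), the surface receptor gene Cd5 (75.4% to 63.1%) and Lef1, a transcription factor of early T cells (41.8% to 30.3%). By equal weights these differed by -3.14, -1.72 and -3.60 points and none was called. The medians stood at percentiles 67.6 and 64.5. No B cell gene end among 12 was called, and the list median of 0.0320 points stood at percentile 95.7. The body of Cd37, a tetraspanin gene of B cells, rose from 77.4% to 91.7% (Fisher's exact test, adjusted p = 2.1e-12), and was the only call in 16 B cell bodies (percentile 70.2). In the NK and cytotoxic list none of 6 gene ends and 1 of 4 bodies was called, Tbx21, which encodes T-bet (57.2% to 45.5%), with -9.30 points and no call by equal weights. In the erythroid and platelet list none of 5 gene ends and 1 of 6 bodies was called, Gata1 (82.5% to 66.3%), with -5.24 points and no call by equal weights. Medians of these lists lay at percentiles 50.99 and 34.4 at gene ends and at 65.1 and 9.6 in bodies.

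Genes of T cell activation and exhaustion had a higher median at gene ends than most matched lists, 0.437 points at percentile 97.9. Many list medians were compared, and 4 of these 8 gene ends were below 0. Of 8 gene ends 1 was called, Lag3, an inhibitory receptor gene, which rose from 55.4% to 88.9% on 3 cytosines with 65 and 36 reads and was not called in the scaled test. In bodies, at percentile 59.7, Tnfrsf9, the gene of the costimulatory receptor 4-1BB, fell from 67.8% to 51.2% and Il2ra, that of the interleukin 2 receptor alpha chain, from 61.6% to 46.6%. By equal weights neither was called (-7.13 and -5.86 points), and the body median went to percentile 0.24. Among cytokine and chemokine genes no gene end of 12 was called (percentile 91.6; Ccl3 and Ccl4 share a gene end, and with it counted once the median was -0.186 points in place of -0.0675), and 1 of 6 bodies was, Il4, from 53.4% to 31.7% (percentile 48.5). Il4 was not called on forward-strand cytosines alone (-14.3 points; Fisher's exact test, adjusted p = 0.142). Of 11 interferon gene ends 1 was called lower, Ifit3, from 67.8% to 46.9%. Of 10 interferon bodies 2 were called lower, Rsad2, the antiviral gene of viperin, from 86.7% to 52.4% on 4 cytosines, and Oas1a from 97.9% to 68.6% on 3 cytosines. The medians of the interferon list lay at percentiles 75.2 and 88.8, the latter 98.9 by equal weights. Thinned to equal reads, Il4, Ifit3 and Oas1a differed by -18.2, -23.5 and -28.6 points and were not called. None of Il4, Ifit3, Rsad2 and Oas1a was called in the scaled test.

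Imprinted genes, methylated on the copy from 1 parent, had the lowest list of gene ends. Of 24 measured, 6 were called lower and none higher, and 21 were below 0. The median fell by 5.96 points, at percentile 0.01 of matched lists, whose middle 95% spanned -4.48 to -0.917. Gnasas1, the antisense transcript of the Gnas cluster, fell from 56.7% to 17.0%, H19, a noncoding RNA gene beside Igf2, from 52.5% to 29.0%, and Gnas, encoding a G protein subunit, from 29.4% to 15.1%. The body of Mest fell from 36.0% to 16.02%. Imprinted bodies had 4 of 21 called lower, and their median lay at percentile 74.3 by pooled reads and at 0 by equal weights, below all 10000 random lists. The counts of 6 gene ends and 4 bodies called lower held by equal weights, with H19 at -13.9 points. Peg10 and Sgce share a gene end, and with it counted once the median was -5.80 points. The 34 windows of 30 to 60% at imprinted genes, compared after the data were seen, had a median of -5.35 points, against -5.36 in other windows of like level (percentile 50.2), and 1 was called lower. On reverse-strand cytosines alone Gnasas1 differed by -16.7 points and was not called.

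**Figure D4:**
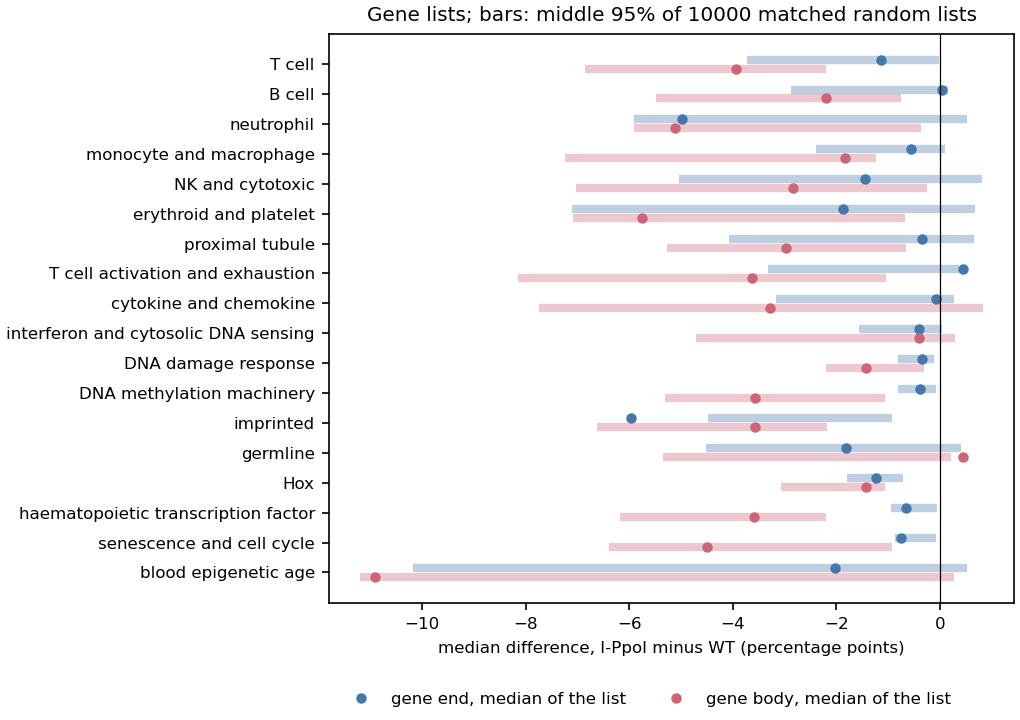
Median difference (I-PpoI minus WT, percentage points) of each gene list at gene ends and in gene bodies (points), with the middle 95% of 10000 matched random lists (bars). The imprinted gene ends, at -5.96 points, lie below their bar, and germline gene bodies and the T cell activation and exhaustion gene ends lie above theirs.

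Genes of the DNA damage response showed no call in 22 gene ends or 22 bodies. The gene ends had a median WT level of 4.41%, and a region under 10% in WT cannot fall by the 10 points asked. The body of Cdkn1a, which encodes the cell cycle inhibitor p21, was at 8.66% in WT and 7.14% in I-PpoI, and the gene end of H2ax, the histone marked at breaks, at 4.47% and 4.12%. Their medians lay at percentiles 70.6 and 28.0. Genes of the DNA methylation machinery had no call in 15 gene ends (percentile 58.2), whose median WT level of 4.07% also left little room to fall. Of 15 bodies 3 were called lower by pooled reads (percentile 26.2), none by equal weights. The 3 were Uhrf1, which guides maintenance methylation (78.4% to 61.8%; -0.247 points by equal weights), the methyl-binding gene Mbd1 (78.4% to 63.5%; -5.23 points) and Tet1, encoding a methylcytosine oxidase (38.8% to 26.7%; -2.51 points). Of the blood epigenetic age genes, used in clocks of mouse blood, Hsf4 and Kcns1 fell in the body by 14.3 and 10.9 points, with the median of 3 genes at percentile 3.03 and that of their gene ends at 45.1. By equal weights the body median of -8.81 points lay at percentile 0.16, and Kcns1 missed the 10 points asked. The Hsf4 body was not called at a coverage minimum of 30 reads (-6.29 points), on reverse-strand cytosines alone (-7.09 points), with thinned reads (-8.89 points) or in the scaled test. A window at Fbxl8 and Hsf4 (8:105268001-105269000), chosen after its values were seen, was called lower by the scaled test. It fell from 77.85% to 50.21% over 30 cytosines.

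Transcription factors of blood formation gave 1 gene end called higher and 1 called lower in 16, and 2 bodies called lower in 17, at percentiles 19.8 and 70.1. Runx3, a factor of T cell lineage choice, rose at its gene end from 69.5% to 85.9%, with 29.6 points on the forward strand and -4.17 on the reverse strand. Lmo2 fell from 45.7% to 32.7% at the gene end, but was not called on the forward strand alone (-11.7 points) or the reverse strand alone (-16.6 points). The bodies of the receptor genes Flt3 and Kit fell by 13.7 and 11.6 points by pooled reads, and differed by -2.39 and -5.12 points by equal weights, with no call. Senescence and cell cycle genes had no called gene end in 12 (percentile 6.79), with a median WT level of 4.61%, too low for a fall of 10 points. Of 10 bodies 1 was called lower (percentile 20.1, or 2.47 by equal weights). This was Lmnb1, encoding lamin B1 (38.5% to 26.0%, with -3.51 points and no call by equal weights). Hox genes had 1 gene end called lower in 39, Hoxa7 (26.4% to 15.1%), and 1 body called lower in 32, Hoxb1 (36.0% to 25.7%), at percentiles 41.4 and 86.2. Neither was called by equal weights (-3.90 and -9.44 points). Germline genes, methylated in most somatic tissues, had 2 gene ends called lower in 15, Mov10l1 (80.7% to 58.7% on 3 cytosines) and Dazl (39.8% to 28.8%), at percentile 43.3. Dazl differed by -3.24 points by equal weights and was not called, and Mov10l1 was not called with thinned reads (-23.2 points). In 7 germline bodies with no call the median of 0.443 points lay at percentile 98.3, and by equal weights at 86.2. Proximal tubule genes, markers of the cells that express I-PpoI, gave 1 gene end called lower in 9, the phosphate transporter gene Slc34a1 (52.5% to 37.4%), and 1 body called lower in 12, Ggt1 (59.9% to 46.5%; -0.0807 points and no call by equal weights), at percentiles 82.1 and 38.8. The counts of calls in lists were equal when adjusted over the list alone, except for the neutrophil gene ends given above. Other named list genes that lost their call in the scaled test were Lck, Cd5, Gata1, Ggt1, Il2ra, Uhrf1, Mbd1, Mov10l1, Hoxa7, Runx3 and Lmo2.

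Strands were compared within and between the libraries. On the same 1235746 CpGs at equal depth, the forward and reverse strands of the WT library gave 550 called windows, 272 higher and 278 lower, and those of the I-PpoI library gave 778, 390 higher and 388 lower. Between the libraries the forward strand gave 618 calls, 57 higher and 561 lower, and the reverse strand 630, 76 higher and 554 lower. At full depth on these CpGs, 744 windows were called lower on the forward strand. Of these, 79.2% went the same way on the reverse strand, with a median of -11.3 points there. In uncalled windows of like level and number of cytosines the values were 66.6% and -3.52 points. For the 74 windows called higher on the forward strand at full depth the share was 50%, with a median of 0.109 points.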

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

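The tests of incomplete conversion, of recovery of methylated molecules, of the direction of calls between libraries, of the other strand at called windows, and of added or shared copies of Pgk1 were chosen after the results were seen, the others before.

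Coverage, which the comparisons of levels use as a weight but do not themselves compare, stood out at the Pgk1 gene end. The windows X:106186001 and X:106187001 together had a ratio of I-PpoI to WT reads of 2.02, which is 2.59 times the X chromosome median of 0.780, while the nearest measured windows stood at 1.03 and 0.793 times that median. Reads shared with pseudogenes present in both mice are argued against by this ratio of 2.588, which they would leave near 1, and an inactive X in a female by the other 378 X gene ends under 20% in WT, whose median difference was -0.489 points with none called higher. The same 2.588 fits added copies of the Pgk1 promoter, a sequence often used to drive selection cassettes in engineered mice: a candidate explanation is that the I-PpoI mouse carries such copies, methylated, since the 1850 reads (55.6% of the total) beyond those expected at the median ratio of unmethylated X windows, 0.896, would have to be 68.6% methylated. This was found and tested on the same reads, 11 of 28734 comparable windows had a ratio of at least 1.88, that of the lower Pgk1 window, and the construct was not analysed here, so chance amplification and a change at Pgk1 itself stay open.

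Most called windows were lower in the I-PpoI library, 1663 against 123, and noise alike in both libraries is argued against as the cause of this direction, since it would split calls between the libraries evenly, while at equal depth 90.8% of them were lower on the forward strand and 87.9% (95% Wilson interval 85.2 to 90.3) on the reverse. Depth and incomplete conversion in WT are argued against. After thinning to equal reads, 93.4% of called windows were lower. The mean drop at 40 to 60% methylation was 13.3 times that under 5%. Levels here are means of both libraries, which limits the difference possible under 5% and may raise that ratio. The mean difference at 5 to 20% was also small, at -1.52 points. Unequal recovery of loci within a window is argued against by the size of the differences alone. With cytosines weighted equally in the difference 92.6% of calls were lower, but the p-values behind these calls still came from pooled reads. Strands of a single library gave up to 126% as many called windows as the libraries did, which leaves undecided how many calls noise within a library makes, because strands of single CpGs differ in both libraries (93745 and 97474 calls), but noise in the reads of single strands as the whole cause of the lower calls is argued against by the other strand, whose median there differed from that of uncalled windows of like level and number of cytosines by -7.79 points for calls on the forward strand (95% bootstrap interval -9.58 to -5.91) and -8.94 for calls on the reverse. Single-base variants were not decided: other CpGs within 100 bp of cytosines called lower had a median of -8.58 points (95% bootstrap interval -8.82 to -8.34) against -1.75 near uncalled cytosines of like level, short of the bound of -10 set before. Weaker recovery of methylated molecules in the I-PpoI library stays open. The 34 windows of 30 to 60% at imprinted genes had a median of -5.35 points (95% bootstrap interval over windows -9.90 to -1.49). Other windows of like level had -5.36. The 34 windows lay at 15 genes, and some adjoin. The read ratio of unchanged cytosines over 80% was 0.756 times that of those under 20%. The I-PpoI genotype also stays open, untested with 1 mouse per group. Intervals over windows or cytosines in this paragraph treat them as independent, which neighbours are not. They may be too narrow, and they cover no spread between mice.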

How the results depend on the processing

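The centred differences, list percentiles by equal weights, the other gene end and the removal of CpGs with unlike strands were tested only after the data were seen; the rest were planned. Lower calls outnumbered higher ones at windows, gene ends and cytosines under each alternative run, from 74.9% to 100% of calls. Counts below are lower then higher, and the cause of each shift was not tested unless the alternative itself changes what is counted. Main counts were 1663 and 123 windows, 277 and 34 gene ends, 1253 and 34 gene bodies, and 12986 and 1698 cytosines. At 20 reads windows gave 731 and 49 and the global difference was -1.29 points. At 30 reads windows gave 430 and 26, gene ends 183 lower, bodies 758 and 20, and the global difference was -1.18. On the forward strand cytosines gave 6441 and 843 and bodies 62 higher; on the reverse strand, 6557 and 853, and 60. Thinned reads gave 175 lower gene ends, 393 and 22 bodies, and 5695 and 802 cytosines. An adjusted p under 0.05 gave 24038 and 3929 cytosines. A minimum of 10 points gave 9756 and 1066 windows and 19784 and 3145 cytosines. A minimum of 25 points gave 31 and 7 gene ends and 69 and 0 bodies. A minimum of 40 points gave 277 and 13 windows, 4 and 0 gene ends, 7 and 0 bodies, and 6348 and 589 cytosines. Equal weights gave 456 lower bodies. The scaled test gave 129 and 4 windows, 98 and 9 gene ends, and 428 and 3 bodies. Windows with at least 1 cytosine gave 3087 and 218, and with at least 5 gave 777 and 43. The fold rule of 1.5 gave 6202 and 1185 windows, 614 and 81 gene ends, and 454 lower bodies. Merged strands gave 953 higher cytosines. The global difference was -6.30 as a pooled read share and -2.35 as a mean over windows. Centring on regions of like level gave 937 and 228 windows (80.4% lower against 93.1%) and 164 and 55 gene ends (74.9% against 89.1%). The other gene end gave 18 higher. Single CpGs compared between strands gave 93745 calls in WT and 97474 in I-PpoI, against 1213 and 1236 between libraries, so strands of a CpG differ by more than read noise. Lists outside the middle 95% of random lists under an alternative alone were, by percentile and, unmatched, gene ends of B cell (99.0), neutrophil (0.01), cytokine (97.6), germline (0.49) and Hox genes (0.3) and bodies of epigenetic age genes (1.78), and by the mean, bodies of neutrophil (0.16) and methylation machinery genes (1.75). By equal weights, bodies of neutrophil (0.41), T cell activation (0.24), interferon (98.9), imprinted (0), senescence (2.47) and epigenetic age genes (0.16) went beyond that range and germline bodies (86.2) came inside it. Equal weights ended 20 named calls and thinned reads 21, mostly in bodies, where pooled levels follow coverage. For 68 named regions, 745 of 890 values kept their side of the thresholds, 144 lost the call and 1 reversed, the gene end of Runx3 on the reverse strand (-4.17). Of the 68, 36 lost the call in the scaled test, which missed most simulated drops. No paired analysis was possible because each group has 1 library. The minimum of 5 reads changed nothing to test, as none under 10 is listed; the asymmetric promoter, motif and recognition site alternatives were not run. Depth limits calls of single cytosines, which fell with thinned reads although weighting plays no part there.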

Other observations

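The tests of cell mix were planned before the data were examined, with list medians as the measure and list means as an alternative. The equal-weight percentiles and the windows named next were chosen after their values were seen.

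Outside protein-coding genes, 3 windows and the second Pgk1 window made up the 4 that the scaled test called higher. The window 14_54297001, at 14:54297001-54298000 over the lncRNA gene Gm43305, rose from 36.9% (34.3 to 39.6) to 90.7% (87.4 to 93.3) over 20 cytosines, while its reads fell from 1290 to 378. The window 18_45024001, at 18:45024001-45025000, rose from 48.8% to 92.5% over 8 cytosines with 697 and 783 reads, and the nearest gene in the table was the lncRNA gene Gm31706. The window 8_66603001, at 8:66603001-66604000, rose from 40.2% to 77.4%, and its neighbour 8_66604001 from 43.3% to 85.9% by Fisher's test, with the neuropeptide Y receptor gene Npy5r the nearest gene. In each of these windows 100% of cytosines moved the same way. Lower windows that the scaled test also called lay in Begain, where 131 cytosines fell from 50.4% to 23.1%, in Zfp503 (82.2% to 56.8%), in Mpo, the gene of neutrophil myeloperoxidase (82.1% to 54.9%), and in Socs3, which encodes a suppressor of cytokine signalling (73.4% to 47.5%).

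Outside the chromosomes compared, 9839 shared cytosines of the Y chromosome had pooled levels of 75.9% in WT and 68.4% in I-PpoI, and means of 70.7% and 69.4%. Reads over these Y cytosines numbered 1105116 in WT and 474741 in I-PpoI. The 123 shared mitochondrial cytosines had pooled levels of 7.57% and 6.76%. The 528934 cytosines listed in WT alone had a mean level of 75.7% and a median coverage of 15 reads, against 49.6% and 12 reads for the 101113 listed in I-PpoI alone.

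Among blood cell marker lists, neutrophil genes had more gene ends called lower than the others, 4 of 11, but from a higher median WT level (66.9%). A hypothesis is that the samples held another mix of blood cells. By the planned measure, the medians of the T cell, B cell and neutrophil lists all lay in the middle 95% of random lists. That was the outcome set beforehand against another mix. The neutrophil mean over gene bodies, an alternative measure, stood at percentile 0.16, in the direction another mix needs. The means of T cell and B cell bodies, at 70.6 and 97.0, did not pass the opposite bound it also needs. A mean follows the 3 of 10 neutrophil bodies called lower where a median need not. For this reason, raised after the values were seen, the medians were not taken to settle it. An equal loss at all gene bodies needs every blood cell list inside those bounds, as the medians were: the lowest stood at percentile 6.63 in bodies, and at 6.555 with gene ends counted too. By equal weights of cytosines the neutrophil body median went to percentile 0.41, with T cell and B cell bodies at 32.6 and 28.7. The equal-weight means of neutrophil, T cell and B cell bodies stood at 0.1, 90.6 and 85.7, and the lymphoid lists again did not pass the opposite bound. Low neutrophil values are picked from many lists and measures and do not exclude an equal loss. With 10 bodies and 11 gene ends measured for neutrophils and 1 mouse per group, these explanations cannot be told apart.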
